A study of Homo sapiens with 18 samples.

How the data were processed

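Single-cell RNA sequencing had been performed on cells from human mesenteric arteries, the vessels that supply the gut, of non-diabetic and diabetic donors. Cells of the intima, the inner layer lined by endothelium, made up 15 libraries, and cells of whole arteries made up 3. The labels gave 18 libraries from 13 numbered donors: 5 non-diabetic and 5 diabetic intima donors, 2 non-diabetic whole-artery donors and 1 diabetic whole-artery donor. Where the labels gave several libraries under 1 donor number, their counts were summed, so that the donor was the replicate. The labels do not say whether any intima donor also gave a whole artery. For 7 of the libraries, from 4 donors, the labels state that the reads had been deposited earlier, and this was used as a batch.

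Per the labels, libraries were made with the 10x Genomics single-cell 3' kit, chemistry version 3.0, which counts each captured molecule once by a unique molecular identifier (UMI) near the 3' end of its transcript. Per the submitters' processing notes, reads were processed with Cell Ranger 6.1.1 on genome build GRCh38. The gene annotation release, the cell calling settings and any removal of free RNA or doublets are not given in the sources used here. The values deposited by the authors are raw UMI counts per gene and cell, whole numbers over 36601 features, with no normalization. Gene positions are given on GRCh38 from GENCODE release 29, matched by the Ensembl identifier in the deposited feature lists.

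The files held 30313 barcodes and 127780044 UMIs. A cell was kept with at least 200 detected genes, at least 500 UMIs and under 20% of UMIs from mitochondrially encoded genes. Doublets were called with the scrublet implementation in scanpy at an expected rate of 6%, in libraries with at least 100 kept cells. The caller marked 172 of 17893 cells (0.961%), between 0.062% and 3.45% of a library, well below the expected rate, so that remaining doublets cannot be ruled out. These cells were removed and 17862 stayed. Counts were scaled per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and a graph of 15 neighbours was clustered with the Leiden algorithm at resolution 1 into 44 clusters, with no batch integration. Clusters were named from marker lists of 19 cell classes fixed before the data were examined. A name needed at least 3 markers detected in at least 20% of the cluster's cells. A cluster stayed unnamed where a class of another lineage reached 0.5 times its score or marked more of its leading genes. So did cluster 12 (545 cells, closest to endothelial), with few UMIs and no leading marker. These rules left 7 clusters with 2028 cells (11.4%) unnamed, and the others fell into 14 classes, called endothelial-like, macrophage-like and so on. The thresholds of this naming rule were set after the clusters had been seen.

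Raw counts were summed per donor and class. A donor entered a comparison with at least 20 cells of the class and 20000 UMIs in its sum. Genes were filtered with filterByExpr, normalized by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 (robust fit, Benjamini-Hochberg adjusted p under 0.05, two-sided), diabetic against non-diabetic intima without covariates, and intima against whole artery with diabetes as a covariate. Standard errors of log2 fold changes were derived from the same fit. Fold changes are log2 ratios from this fit, while levels are means over donors of CPM (a gene's UMIs scaled to 1e6 UMIs of the donor's sum) after TMM scaling within the comparison, with their SD over donors. Values of whole arteries given without a test are CPM of the summed counts without scaling. Where all donors of a group were at 0, a lower bound against 3 counts over the group was used, and with 1 to 3 counts the ratio of summed counts with its exact 95% interval, which covers counting error only. DESeq2 1.42.0 and limma 3.58.1 (voom) were run as alternatives. Genes on the Y chromosome and genes of X inactivation were left out of all tests.

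Before the data were examined, 21 gene lists were fixed, besides the ribosomal protein genes, the mitochondrially encoded genes and the markers of other cell classes that a preparation could hold. Lists were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists within a comparison. The genes named in the text were also fixed by rule: per comparison the 8 largest rises and 8 largest falls among genes past the threshold with a mean log2 CPM of at least 5, with free places filled by the smallest unadjusted p as values without a call, a set of genes always given, and up to 4 members with the smallest p of each list described. Some genes that this rule names are not reported here. Called genes outside the rule are named where there were at most 5 calls. Shares of cell classes per donor were compared by two-sided exact permutation tests in donors with at least 100 kept cells, for classes reaching 1% of cells in any donor. The share of macrophage-like cells with a TREM2 UMI was compared after thinning each cell to 500 UMIs. With 1 diabetic donor, whole arteries were not tested between diabetic and non-diabetic donors.

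Each test was run on simulated counts with the means and library sizes of the real donors and 200 changed genes. In endothelial-like cells, diabetic against non-diabetic, 90 of 99 genes changed 8-fold and 6 of 97 changed 2-fold were recovered among 12679 genes. In macrophage-like cells the test recovered 82 of 99 and 2 of 99 among 10873, and in T cell-like cells 77 of 98 and 1 of 99 among 10999. Between intima and whole artery it recovered 95 of 100 and 15 of 99 in endothelial-like cells (9091 genes), 67 of 99 and 3 of 98 in macrophage-like cells (9532 genes), and 96 of 98 and 8 of 93 in fibroblast-like cells (3777 genes). The 6 tests made 10, 9, 6, 7, 1 and 8 calls among unchanged genes, in this order. At these numbers of donors a 2-fold change was therefore mostly beyond reach.

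Alternatives concerned the normalization, the test, the gene filter, stricter and looser cell filters, doublets, donor minimums, naming by each cell's own marker counts, a batch term, the replicate number as a block, leaving out each donor, and others given with their values in the closing section. The tests of smooth muscle-like cells between diabetic and non-diabetic intima and between intima and whole artery, and of fibroblast-like cells between diabetic and non-diabetic intima, were not run, since too few donors passed the minimum. Analyses used R 4.3.3 and Python 3.11.15 with scanpy 1.11.5, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1 and scikit-learn 1.9.0, and figures matplotlib 3.10.9.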

Results

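Cells had been taken from the intima, the inner layer of the artery that faces the blood, and from whole mesenteric arteries of non-diabetic donors and of donors with type 2 diabetes. From its title, the series asked how endothelial cells and macrophages interact in diabetic arteries, with TREM2, a lipid-sensing receptor of macrophages, as the molecule of interest. The deposited counts came from 18 libraries and 13 numbered donors. Depth was very uneven. The 12 deeper libraries held between 1540992 and 33895222 UMIs and kept between 238 and 3218 cells each, with medians of 892.5 to 10566 UMIs per kept cell. The other 6 libraries, from non-diabetic intima donors 2 and 4 and diabetic intima donors 4 and 5, held between 28650 and 213694 UMIs and kept 4 to 51 cells each, so that these 4 donors entered no comparison of genes. Hemoglobin RNA, which comes from red blood cells, took 70.0% of the UMIs of non-diabetic intima donor 3, 21.2% of those of diabetic intima donor 3, and 10.4% and 5.33% in the pair of libraries from non-diabetic intima donor 1. All 52 pairs of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom between 1.71 and 646, so no library was counted as a repeat of another.

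The 17862 kept cells fell into 44 clusters, most of which carried the markers of a vascular or immune cell class. Endothelial-like clusters were led by genes such as EDN1, which encodes the vasoconstrictor endothelin, and SOX18. Macrophage-like clusters were led by C1QA and C1QB of the complement system, VSIG4, CD163 or LYVE1, or by CCL3L1 and APOE (cluster 8) or SPP1, CCL18 and GPNMB (cluster 17). T cell-like clusters were led by CD3D, TRAC, GZMK or IL7R. Smooth muscle-like, fibroblast-like, NK cell-like, B cell-like, monocyte-like, neutrophil-like, mast cell-like, plasma cell-like, dendritic-like, glial-like and erythroid-like clusters were also found. Endothelial-like cluster 14 was led in part by PTGS2, EGR1 and CCL2, which belong to stress and inflammatory responses. Macrophage-like cluster 23 and T cell-like cluster 28 were led by the proliferation genes MKI67 and TOP2A. Many clusters came mainly from 1 donor: 99.3% of the endothelial-like cells of diabetic intima donor 1 lay in cluster 1, 97.5% of those of diabetic donor 3 in cluster 14 and 94.1% of those of non-diabetic donor 1 in cluster 7. Unnamed clusters held 10.5% of the cells of non-diabetic intima, 8.86% of diabetic intima, 16.0% of non-diabetic whole artery and 26.3% of diabetic whole artery.

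Macrophage-like cells made up a larger part of the diabetic than of the non-diabetic intima in every donor with enough cells. Their share of kept cells was 28.8% ± 4.82 (SD, n = 3, between 24.2% and 33.8%) in diabetic donors and 6.04% ± 3.40 (n = 3, between 2.60% and 9.40%) in non-diabetic donors. The groups did not overlap, yet the two-sided exact permutation test gave p = 0.1, the smallest value that 3 against 3 donors allow, and an adjusted p of 0.8 over the 10 classes tested. No class passed the threshold, which this design cannot reach. Counted among immune cells alone, macrophage-like cells made up 44.3% ± 2.94 and 23.4% ± 14.5 (exact permutation p = 0.1). Among the donors whose reads had been deposited earlier, 2 diabetic and 2 non-diabetic, the difference in share was 23.0 percentage points, beside 22.7 over all 6 donors.

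The other 9 classes tested overlapped between the groups, while plasma cell-like cells, not tested, made up 0.402% to 0.853% of diabetic and 0% to 0.201% of non-diabetic intima. T cell-like cells made up 25.4% ± 6.23 of diabetic and 17.4% ± 16.2 of non-diabetic intima (SD, n = 3 each; exact permutation p = 0.5), and endothelial-like cells 24.6% ± 8.95 and 19.7% ± 16.8 (exact permutation p = 0.7). The difference in endothelial-like share turned to -3.03 percentage points without non-diabetic donor 3 and -0.223 without diabetic donor 1, and that in T cell-like share to -0.0738 without non-diabetic donor 5. B cell-like cells made up 0.706% ± 0.646 and 3.25% ± 2.53 (exact permutation p = 0.2). Fibroblast-like cells made up 62.6% of the cells of non-diabetic donor 5 and at most 3.32% of those of a diabetic donor. Erythroid-like cells averaged 0.561% ± 0.147 in diabetic and 8.76% ± 14.5 in non-diabetic intima, and reached 25.5% in non-diabetic donor 3.

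**Figure D1:**
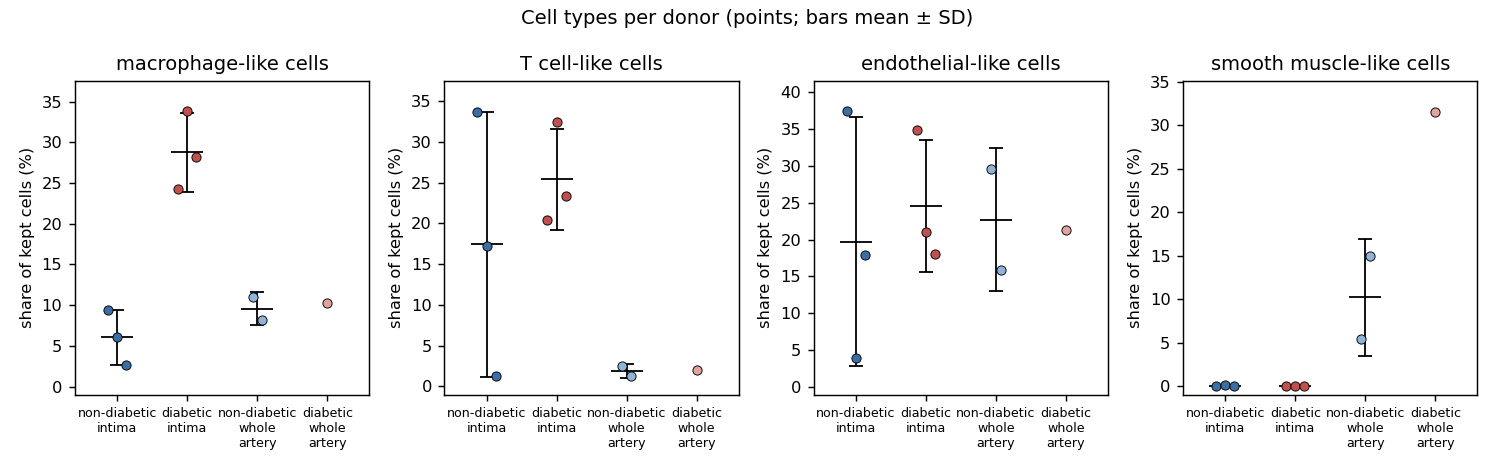
Share of kept cells (%) of macrophage-like, T cell-like, endothelial-like and smooth muscle-like cells in donors with at least 100 kept cells, by group, with 1 point per donor and bars for the mean and SD of groups of 2 or more donors. Macrophage-like shares of the diabetic intima, between 24.2% and 33.8%, all lie above those of the non-diabetic intima, between 2.60% and 9.40%.

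Chemokine and early response genes had the smallest p-values in macrophage-like cells of diabetic against non-diabetic intima, though none passed the threshold. CCL4 (ENSG00000275302, chromosome 17, 36103590 to 36105621) and CCL3 (ENSG00000277632, chromosome 17, 36088256 to 36090169) encode chemokines that draw leukocytes. CCL4 stood at 426 ± 96.6 CPM in diabetic (SD, n = 3) and 9.28 ± 9.61 in non-diabetic donors (n = 2), a log2 fold change of 5.28 ± 0.69 (SE), with an adjusted p of 0.0624 in edgeR's quasi-likelihood test. CCL3 stood at 812 ± 301 and 49.2 ± 23.8 CPM (4.01 ± 0.60, edgeR adjusted p 0.0878). Each has a near-identical copy in the genome, so that counts may be split between copies. CD83 (ENSG00000112149, chromosome 6, 14117256 to 14136918), a marker of activated antigen-presenting cells, stood at 126 ± 37.3 and 7.52 ± 3.45 CPM (4.22 ± 0.57, edgeR adjusted p 0.0624). CXCL8, the main neutrophil-attracting chemokine, stood at 138 ± 71.2 and 4.58 ± 4.08 CPM, and NR4A2, an early response transcription factor, at 202 ± 109 and 13.9 ± 5.52 CPM (edgeR adjusted p 0.102 for each). CXCL3 had 2407 UMIs in diabetic and 3 in non-diabetic donors, a ratio of 70.5 with a 95% counting interval of 24.1 to 342. ATF3 and IFRD1, also stress-responsive, had log2 fold changes of 3.10 and 2.34 (edgeR adjusted p 0.154 for each).

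Genes with lower values in diabetic macrophage-like cells included markers of blood monocytes and neutrophils. S100A8, a calcium-binding protein abundant in both, stood at 168 ± 69.2 CPM in diabetic (SD, n = 3) and 2255 ± 2685 in non-diabetic donors (n = 2), with an edgeR adjusted p of 0.647. Its log2 fold change of -3.74 was -1.06 without non-diabetic donor 3, and -4.53 without non-diabetic donor 1, where it passed. PLAC8 stood at 11.49 ± 3.73 and 90.2 ± 81.8 CPM (log2 fold change -3.01 ± 0.56, edgeR adjusted p 0.208), and CFP, which encodes the complement factor properdin, at 21.3 ± 12.9 and 108 ± 72.6 CPM. PRDX2 (-2.75) and SLC25A37 (-2.74), both abundant in red blood cells, lay lower as well. CYTOR, PPA1 and RRP7A had log2 fold changes of -1.72, -1.51 and -1.52. PRDX2 and SLC25A37 came to -1.28 and -0.82 without non-diabetic donor 3, and PLAC8 and RRP7A to -1.39 and -0.90 without non-diabetic donor 1.

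In macrophage-like cells edgeR's quasi-likelihood test called 0 of 10873 genes between 3 diabetic and 2 non-diabetic donors, with 630 genes at an unadjusted p under 0.05 where chance gives 544. DESeq2 called 45 genes and limma-voom 0. Groups did not overlap for 2514 genes (23.1%), against 20% by chance. Leaving out diabetic donor 1, diabetic donor 2, non-diabetic donor 1 or non-diabetic donor 3 gave 3, 20, 26 and 6 genes, and a term for the earlier deposit gave 6. Within the earlier deposit, 2 diabetic donors against 1 non-diabetic donor assumed to vary like them, 38 genes passed, 9 higher and 29 lower. Most macrophage-like cells lay in cluster 8 in diabetic donor 1 (63.9%), cluster 17 in diabetic donor 3 (51.9%) and cluster 0 in diabetic donor 2 (66.6%) and non-diabetic donor 3 (64.3%), while non-diabetic donor 1 was spread over clusters 0 and 8 (43.9% and 36.9%).

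TREM2 (ENSG00000095970, chromosome 6, 41158506 to 41163186) stood at 122 ± 34.4 CPM in macrophage-like cells of diabetic intima (SD, n = 3) and 49.99 ± 21.4 in those of non-diabetic intima (n = 2). Its log2 fold change was 1.24 ± 0.45 (SE), with an adjusted p of 0.766 in edgeR's test (0.0177 unadjusted). The difference did not pass. APOE (ENSG00000130203, chromosome 19, 44905754 to 44909393), a lipid carrier and TREM2 ligand, stood at 4974 ± 2065 and 1585 ± 742 CPM (1.65 ± 0.61, edgeR adjusted p 0.766). GPNMB, a glycoprotein of lipid-laden macrophages, stood at 494 ± 372 and 73.1 ± 85.7 CPM (2.69 ± 1.00, edgeR adjusted p 0.811). Without non-diabetic donor 1 the log2 fold change was 5.41 for GPNMB and 1.89 for TREM2. The log2 fold change of TYROBP, the signalling partner of TREM2, was -0.00 ± 0.68, with 2697 ± 1287 and 2697 ± 2497 CPM, and took the other sign under most alternatives, for example 1.62 without non-diabetic donor 1. SPP1, which encodes osteopontin, stood at 676 ± 1010 and 145 ± 130 CPM, and its log2 fold change of 2.25 turned to -0.56 without diabetic donor 3. LYVE1, a marker of resident perivascular macrophages, stood at 131 ± 85.5 and 289 ± 194 CPM, CD9 at 209 ± 142 and 77.4 ± 106 CPM, and the cytokine gene IL1B at 110.5 ± 79.3 and 42.2 ± 49.2 CPM (edgeR adjusted p 0.961, 0.974 and 0.969). The log2 fold change of CD9 turned to -0.24 within the earlier deposit.

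**Figure D2:**
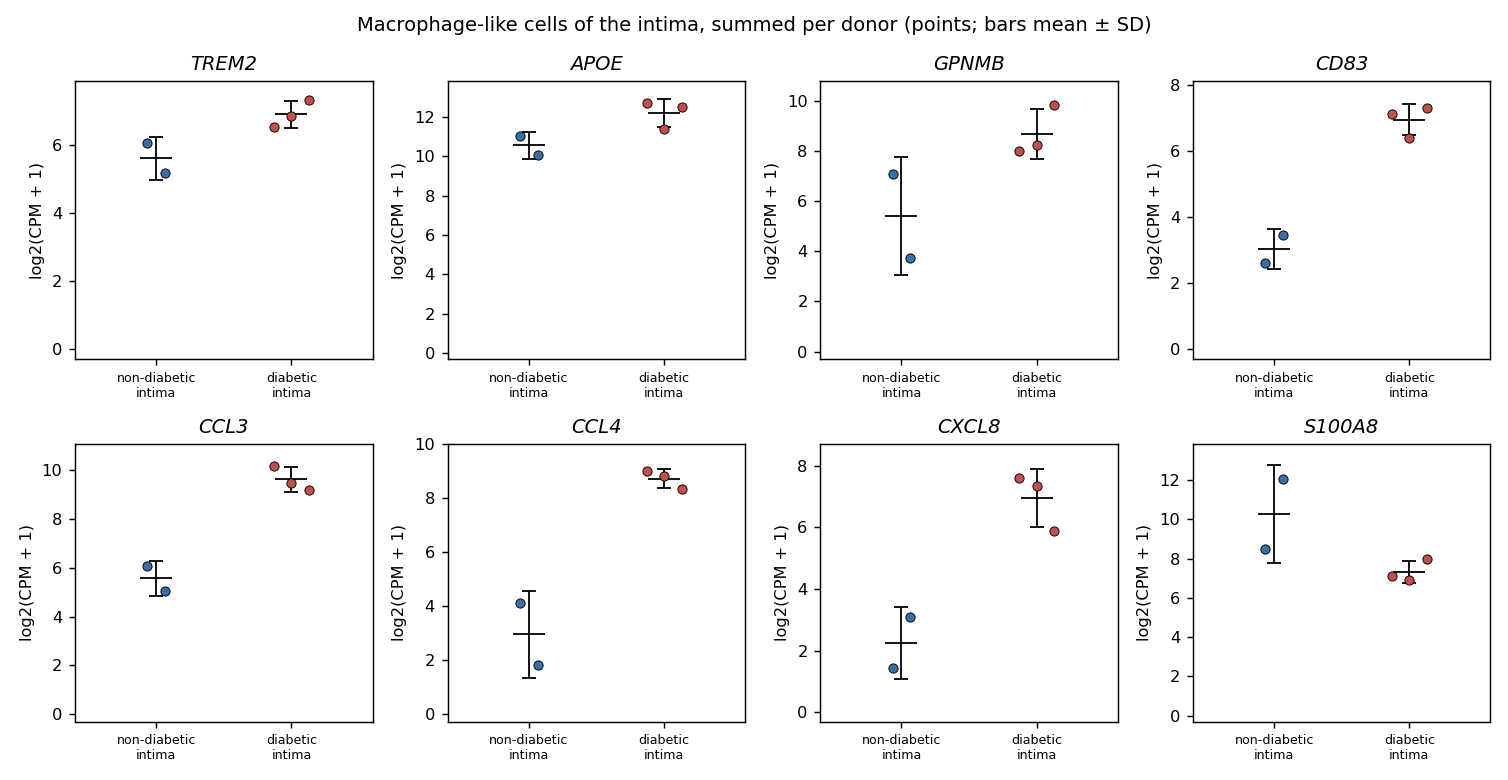
TREM2, APOE, GPNMB, CD83, CCL3, CCL4, CXCL8 and S100A8 as log2(CPM + 1) in macrophage-like cells of non-diabetic (n = 2) and diabetic (n = 3) intima, with 1 point per donor and bars for the mean and SD. On the CPM scale TREM2 averages 122 in diabetic and 49.99 in non-diabetic donors.

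Of the gene lists fixed beforehand, those of inflammatory macrophages and of immediate early genes had the smallest camera p in macrophage-like cells, both higher in value in diabetic intima. Of 13 inflammatory macrophage genes, 0 passed the test over all genes and 7 higher and 1 lower passed adjusted over the list alone, with a median log2 fold change of 3.26. Camera gave an adjusted p of 2.75e-15, and adjusted p = 0.293 with an estimated correlation. Its members CCL3, CCL4, CXCL8 and CXCL2 (183 ± 202 against 9.66 ± 3.10 CPM) lay higher and S100A8 lower. Of 18 dissociation and immediate early genes, 11 passed as higher adjusted over the list alone, with a median of 1.93 (camera adjusted p = 1.76e-15, adjusted p = 0.293 with an estimated correlation). Among them FOSB stood at 371 ± 205 and 37.4 ± 17.7 CPM and JUN at 1123 ± 620 and 161 ± 122 CPM, both transcription factors induced within minutes of a stimulus. The list of leukocyte adhesion and NF-kB genes (13 genes, 4 higher adjusted over the list alone) had a median of 1.46, or 1.09 with members at their bounds (camera adjusted p = 3.71e-08, adjusted p = 0.293 with an estimated correlation). TNFAIP3, a feedback inhibitor of NF-kB, stood at 64.2 ± 22.0 and 23.4 ± 9.15 CPM.

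The lipid-associated list that includes TREM2 had 18 measured members, 16 of them with positive fold changes and a median of 0.89. None passed over all genes or adjusted over the list alone (0 of 18), while camera gave an adjusted p of 3.37e-05, and adjusted p = 0.443 with an estimated correlation. ABCG1, a cholesterol exporter, stood at 59.6 ± 15.1 and 23.1 ± 11.6 CPM. Macrophage-derived factors (14 genes, 1 higher adjusted over the list alone, median 1.34) had a camera adjusted p of 4.53e-05, and adjusted p = 0.318 with an estimated correlation. Among them the growth factor gene HBEGF stood at 52.1 ± 32.6 and 13.4 ± 4.92 CPM, and TNF had 481 and 3 UMIs, a ratio of 14.1 (4.79 to 68.5 from counting error alone), and non-diabetic donor 3 had none. Macrophage receptors for endothelial ligands (18 genes, median -0.04, camera adjusted p = 0.431) and resident perivascular genes (10 genes, median 0.24, mean -0.08, camera adjusted p = 0.644) showed no shift. The endothelial ligand list, measured in the same cells, had a median of 0.52 (11 genes, camera adjusted p = 0.0709), and the endothelial receptor list one of 0.42 (11 genes, camera adjusted p = 0.189).

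Other lists in diabetic macrophage-like cells moved in both directions, with a camera adjusted p under the threshold for 16 in all and for 0 with an estimated correlation. Matrix genes (10 genes, 0 adjusted over the list alone, median 1.14, camera adjusted p = 0.00135, adjusted p = 0.293 with an estimated correlation) and synthetic smooth muscle genes (7 genes, 2 higher and 1 lower adjusted over the list alone, median 2.00, camera adjusted p = 0.00483, adjusted p = 0.293 with an estimated correlation) lay higher. Of the latter, the transcription factor gene KLF4 stood at 178 ± 66.1 and 42.9 ± 21.9 CPM and VCAN lower (23.8 ± 10.7 and 68.1 ± 23.3 CPM). Endothelial quiescence genes, of which KLF2 and KLF4 are also early response genes, had a median of 1.08 (6 genes, 1 higher adjusted over the list alone, camera adjusted p = 0.00764, adjusted p = 0.443 with an estimated correlation). Angiogenesis genes had a median of 0.69 (6 genes, camera adjusted p = 0.0105, adjusted p = 0.443 with an estimated correlation) and MHC class II genes one of 0.58 (8 genes, camera adjusted p = 0.0112, adjusted p = 0.583 with an estimated correlation). Metallothioneins, which bind zinc and copper, had a median of -1.41 (5 genes, camera adjusted p = 0.00633, adjusted p = 0.447 with an estimated correlation), with MT2A at 118 ± 31.2 and 309 ± 257 CPM. Not called were hypoxia (median -0.03, mean 0.31, camera adjusted p = 0.823), interferon (-0.88, 0.12), oxidative phosphorylation (-0.15, 0.15), lipid uptake (-0.27, 0.426), antioxidant (-0.14, 0.36) and contractile smooth muscle genes (1.14, 0.475).

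Markers of other cell types moved in the same comparison. In diabetic macrophage-like cells, monocyte markers had a median log2 fold change of -1.46 (7 genes, 2 lower adjusted over the list alone, camera adjusted p = 4.59e-05, adjusted p = 0.293 with an estimated correlation). Plasma cell markers had one of -2.46 (7 genes, 3 lower adjusted over the list alone, camera adjusted p = 0.000495, adjusted p = 0.447 with an estimated correlation). Erythroid markers had one of -5.49 (4 genes, camera adjusted p = 0.0079, adjusted p = 0.447 with an estimated correlation). T cell markers lay higher, with a median of 3.14, or 2.49 with members at their bounds (7 genes, camera adjusted p = 0.000221, adjusted p = 0.443 with an estimated correlation). Not called were NK cell markers (median 4.04, or 2.07 at bounds, camera adjusted p = 0.0927), dendritic markers (-0.85, 0.0927), mast cell markers (-4.09, 0.424) and endothelial markers (0.63, 0.26). Ribosomal protein genes had a median of -0.31 (82 genes, camera adjusted p = 4.72e-05, adjusted p = 0.583 with an estimated correlation) and mitochondrially encoded genes one of 0.33 (13 genes, camera adjusted p = 0.108).

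The share of macrophage-like cells with a TREM2 UMI depended on depth. Without thinning, 27.1% ± 4.71 of the cells of diabetic donors (SD, n = 3) and 15.3% ± 4.02 of those of non-diabetic donors (n = 2) had one (exact permutation p = 0.2, the smallest value possible). After each cell was thinned to 500 UMIs, which left out 0 cells, the shares were 5.29% ± 1.24 and 4.88% ± 1.94, a difference of 0.402 percentage points (two-sided exact permutation p = 0.8). The difference turned to -0.966 without non-diabetic donor 1, to -0.128 without diabetic donor 3 and to -0.155 with the looser cell filter, and it was 1.77 without non-diabetic donor 3 and 0.254 without diabetic donor 2. The thinned shares ordered the donors differently from TREM2 CPM, so no order is read from them. Among donors of the earlier deposit, 2 diabetic and 1 non-diabetic, it was 1.24 percentage points. In endothelial-like cells, which should lack TREM2, at most 0.217% of a donor's cells had a TREM2 UMI after thinning and 1.35% before it. Median depths were 1178.5 to 9266 UMIs in macrophage-like and 4843 to 13870 in endothelial-like cells of these donors.

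In endothelial-like cells, VIPR1 was lower in diabetic than in non-diabetic intima, and it was the 1 gene that passed the test. VIPR1 (ENSG00000114812, chromosome 3, 42489299 to 42537573) encodes a receptor for vasoactive intestinal peptide, a vasodilator. It stood at 2.18 ± 0.405 CPM in diabetic (SD, n = 3) and 42.4 ± 17.8 in non-diabetic donors (n = 3), with a log2 fold change of -4.37 ± 0.43 (SE) and an edgeR adjusted p of 0.00283. It lies below the mean level set for named genes and is named here after its values were seen. Its adjusted p rose to 0.0939 without non-diabetic donor 1 and to 0.0661 without non-diabetic donor 5. No gene rose.

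Early response and stress genes stood higher in diabetic endothelial-like cells without passing the threshold. IER3 (ENSG00000137331, chromosome 6, 30743199 to 30744554), an early response gene that protects from cell death, stood at 1254 ± 769 and 119.8 ± 41.0 CPM (SD, n = 3 each; log2 fold change 3.37 ± 0.60, edgeR adjusted p 0.145). JUN (ENSG00000177606, chromosome 1, 58780788 to 58784327) stood at 1567 ± 686 and 319 ± 76.8 CPM (2.29 ± 0.47, edgeR adjusted p 0.225), and GADD45B, induced by DNA damage and NF-kB, at 562 ± 486 and 59.2 ± 9.31 CPM (3.24 ± 0.59, edgeR adjusted p 0.173). CCL2 (ENSG00000108691, chromosome 17, 34255218 to 34257203), the chief monocyte-attracting chemokine, stood at 327 ± 253 and 39.7 ± 19.7 CPM (3.01 ± 0.72, edgeR adjusted p 0.382). MFAP2 of elastic microfibrils (59.2 ± 30.4 and 9.96 ± 2.82 CPM), the glucose transporter gene SLC2A3 (136 ± 75.8 and 28.2 ± 12.1 CPM), TUSC3 (log2 fold change 2.24), MRPS6 (1.92) and MARCKS (1.72) lay higher as well, with edgeR adjusted p between 0.173 and 0.264.

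Lower in diabetic endothelial-like cells, again without a call, lay PKHD1L1 (ENSG00000205038, chromosome 8, 109362477 to 109530330; 9.58 ± 4.94 and 65.4 ± 28.5 CPM, log2 fold change -2.70 ± 0.46, edgeR adjusted p 0.145). So did PGM5 (ENSG00000154330, chromosome 9, 68328308 to 68531061; 26.8 ± 0.709 and 88.4 ± 26.002 CPM, -1.73 ± 0.32, edgeR adjusted p 0.164), a protein of cell adhesion sites. CPAMD8 stood at 63.9 ± 27.0 and 378 ± 251 CPM, and TCN2, which encodes the vitamin B12 carrier transcobalamin, at 62.8 ± 27.5 and 215 ± 71.4 CPM. CCDC144A (-2.13), TENT5A (-1.41), MFSD6 (-1.35) and NDRG4 (-1.46) lay lower too.

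Adhesion molecules and genes of nitric oxide production did not pass. VCAM1 stood at 227 ± 262 CPM in diabetic and 155 ± 89.6 in non-diabetic endothelial-like cells (SD, n = 3 each) and ICAM1 at 141 ± 101 and 115 ± 13.04 (log2 fold changes 0.56 and 0.29, edgeR adjusted p 0.936 and 0.933). Without diabetic donor 3 these turned to -0.92 and -0.41, and within the earlier deposit to -0.38 and -0.42. SELE, which encodes E-selectin, had a log2 fold change of 2.55 ± 2.40, and -0.78 without diabetic donor 3. The nitric oxide synthase gene NOS3 stood at 88.1 ± 28.1 and 165 ± 95.8 CPM (edgeR adjusted p 0.779). The flow-responsive regulator KLF2 stood at 1438 ± 1100 and 990.5 ± 389 (0.912). The fatty acid binding protein gene FABP4 stood at 2.52 ± 3.45 and 45.8 ± 67.3 (0.777). KLF2's log2 fold change of 0.54 was -6.59e-04 without diabetic donor 3.

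**Figure D3:**
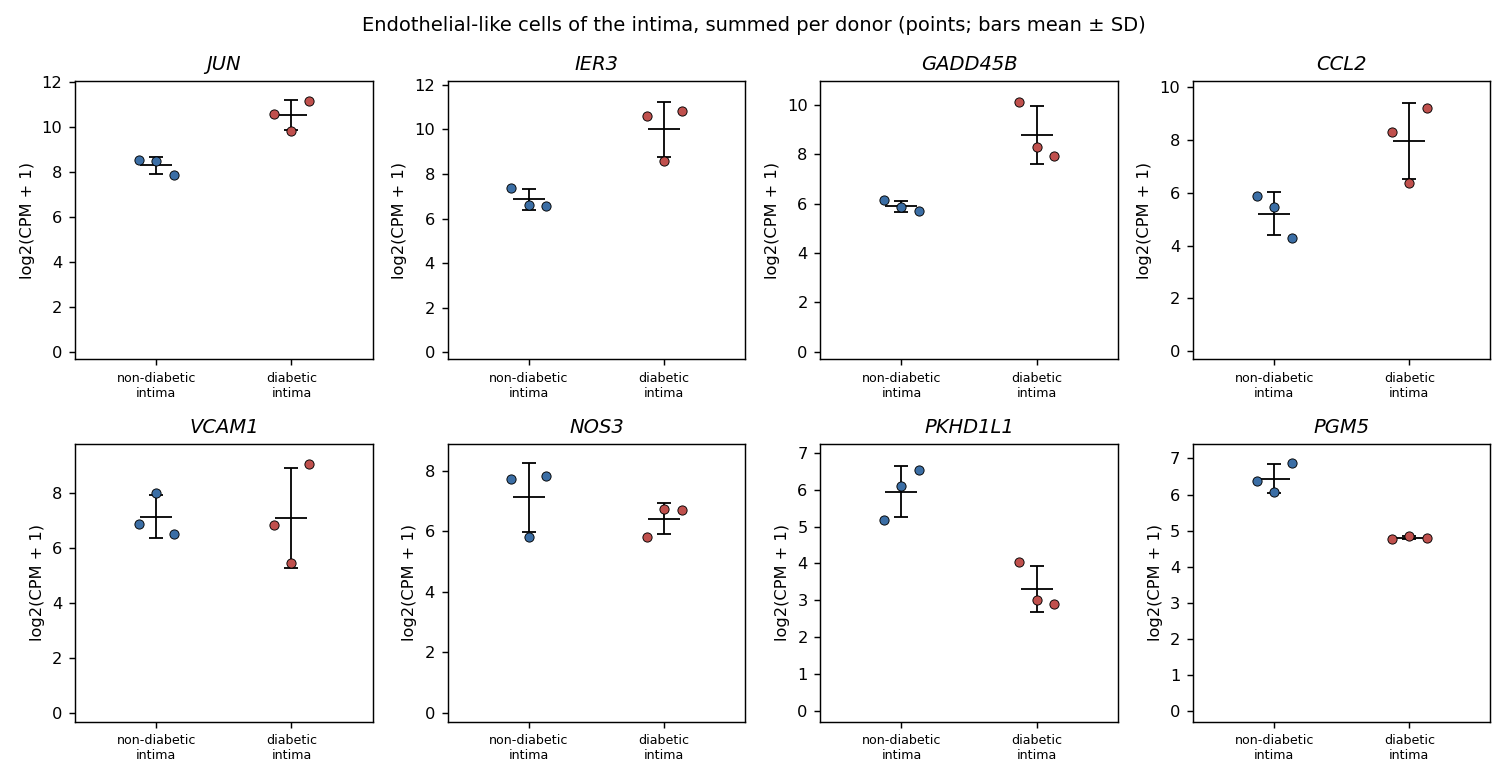
JUN, IER3, GADD45B, CCL2, VCAM1, NOS3, PKHD1L1 and PGM5 as log2(CPM + 1) in endothelial-like cells of non-diabetic and diabetic intima (n = 3 each), with 1 point per donor and bars for the mean and SD. On the CPM scale JUN averages 1567 in diabetic and 319 in non-diabetic donors.

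In endothelial-like cells edgeR called 1 of 12679 genes, with 839 at an unadjusted p under 0.05 where chance gives 634. DESeq2 called 80 and limma-voom 1. Groups did not overlap for 1496 genes (11.8%), against 10% by chance. The count was 2, 20 and 12 without diabetic donors 1, 2 and 3, and 0, 12 and 0 without non-diabetic donors 1, 3 and 5. It was 5 with a term for the earlier deposit and 156 in the 4 donors of that deposit alone. Each donor's endothelial-like cells came mostly from 1 cluster, namely cluster 1 in diabetic donor 1, cluster 3 in diabetic donor 2 (97.8%) and non-diabetic donors 3 and 5 (100% and 76.0%), cluster 14 in diabetic donor 3 and cluster 7 in non-diabetic donor 1.

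Apart from ribosomal protein genes, immediate early genes had the smallest camera p of the lists in diabetic endothelial-like cells. Of 18 such genes, 0 passed over all genes and 8 were higher adjusted over the list alone, with a median log2 fold change of 1.96 (camera adjusted p = 6.69e-13, adjusted p = 0.401 with an estimated correlation). SOCS3, a brake on cytokine signals, stood at 649 ± 378 and 83.9 ± 70.5 CPM and IER2 at 1522 ± 802 and 269.7 ± 175. Inflammatory macrophage genes, measured in endothelial-like cells, had a median of 3.05 (10 genes, 4 higher adjusted over the list alone, camera adjusted p = 1e-07, adjusted p = 0.401 with an estimated correlation). Among them were PTGS2, the inducible cyclooxygenase (648 ± 566 and 109.6 ± 28.7 CPM), and CXCL2 (940.2 ± 699 and 112 ± 55.7 CPM). Adhesion and NF-kB genes had a median of 0.43 (19 genes, 2 higher adjusted over the list alone, camera adjusted p = 0.0128, adjusted p = 0.636 with an estimated correlation). Endothelial ligands for macrophages had one of 0.29 (17 genes, 1 higher adjusted over the list alone, camera adjusted p = 0.0494, adjusted p = 0.589 with an estimated correlation). CXCL12, a chemokine of leukocyte homing, stood at 236 ± 190 and 42.8 ± 28.3 CPM.

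Matrix, antigen presentation and metallothionein genes also shifted by camera in endothelial-like cells. Matrix and mesenchymal transition genes had a median of 0.66 (19 genes, 0 adjusted over the list alone, camera adjusted p = 0.0035, adjusted p = 0.401 with an estimated correlation), with FN1, which encodes fibronectin, at 2795 ± 1503 and 912 ± 281 CPM. MHC class II genes had a median of 0.75 (8 genes, 0 adjusted over the list alone, camera adjusted p = 3.33e-05, adjusted p = 0.401 with an estimated correlation), with HLA-DRA at 779 ± 380 and 202 ± 203 CPM. Metallothioneins had a median of -1.58 (4 genes, 2 lower adjusted over the list alone, camera adjusted p = 1.85e-05, adjusted p = 0.401 with an estimated correlation), with MT1X at 34.1 ± 22.6 and 218 ± 137 CPM. Oxidative phosphorylation genes (15 genes, median 0.38, camera adjusted p = 0.0128, adjusted p = 0.636 with an estimated correlation) and contractile smooth muscle genes (8 genes, median 0.77, camera adjusted p = 0.0147, adjusted p = 0.401 with an estimated correlation) lay higher. Camera called 15 lists in all, 9 without diabetic donor 1, and 0 with an estimated correlation.

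Lists that camera did not call in endothelial-like cells were endothelial quiescence (13 genes, median 0.05, mean -0.10, adjusted p = 0.632), hypoxia (median 0.13, 0.302), angiogenesis (-0.07, 0.608), interferon (-0.72, 0.571), lipid uptake (-0.59, 0.112), antioxidant (-0.17, 0.559), lipid-associated macrophage (-0.26, 0.998), resident perivascular (0.19, 0.792). The same held for macrophage receptors (-0.18, 0.835), macrophage-derived factors (0.07, 0.0576, with 1 of 9 higher adjusted over the list alone), endothelial receptors for macrophage factors (-0.19, 0.578) and synthetic smooth muscle genes (0.23, 0.578). Markers of 5 other cell classes lay higher by camera in the same cells, and none of these lists passed with an estimated correlation. Macrophage markers had a median log2 fold change of 3.01 (8 genes, camera adjusted p = 1.85e-05, adjusted p = 0.401 with an estimated correlation), with the complement gene C1QB at 47.9 ± 58.2 and 1.32 ± 2.29 CPM. T cell markers had one of 2.62, or 2.503 at bounds (4 genes, 3 higher adjusted over the list alone, camera adjusted p = 1.85e-05, adjusted p = 0.401 with an estimated correlation). NK cell markers had one of 1.94 (4 genes, 2 higher adjusted over the list alone, camera adjusted p = 0.0112, adjusted p = 0.401 with an estimated correlation). Monocyte markers had one of 2.75 (3 genes, 0.0439, adjusted p = 0.575 with an estimated correlation) and smooth muscle markers of 1.26 (4 genes, 0.0473, adjusted p = 0.401 with an estimated correlation). Lymphatic (-1.01, 0.632), fibroblast (-0.09, 0.559), mesothelial (-0.83, 0.559, with 1 of 3 lower adjusted over the list alone) and erythroid markers (-1.02, 0.579) were not called. Ribosomal protein genes had a median of 0.79, with 81 of 82 positive (camera adjusted p = 1.15e-18, adjusted p = 0.401 with an estimated correlation). Mitochondrially encoded genes had one of -0.02 (0.835).

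In T cell-like cells of diabetic intima complement, MHC class II and early response genes had higher values and some genes of naive T cells lower ones, again without a gene past the threshold. NR4A2 stood at 79.3 ± 28.5 CPM in diabetic (SD, n = 3) and 8.24 ± 0.52 in non-diabetic donors (n = 2), with a log2 fold change of 3.26 ± 0.51 and an edgeR adjusted p of 0.346. C1QA and C1QB, complement genes of macrophages, stood at 48.9 ± 21.9 and 3.36 ± 1.04 CPM and at 51.7 ± 19.4 and 5.95 ± 0.871 CPM (edgeR adjusted p 0.346 for each). APOE had 528 and 2 UMIs, a ratio of 89.1 (95% counting interval 24.6 to 738). HLA-DRA stood at 302 ± 181 and 27.1 ± 19.7 CPM (edgeR adjusted p 0.593) and TNFAIP3 at 179 ± 70.3 and 37.5 ± 0.818 CPM (0.636). ITM2C (2.05), IER5 (1.65), BTG2 (1.63) and HLA-DMB (2.31) had positive log2 fold changes. Lower lay the lymph node homing receptor gene CCR7 (31.5 ± 9.43 and 133 ± 123 CPM), and the transcription factor genes TCF7 (75.5 ± 11.3 and 172 ± 5.59 CPM) and SATB1 (-1.40). C1orf56 (-1.73), TRABD2A (-1.42), RIC3 (-1.34) and WDR74 (-1.10) were lower in value too, and IFI27 (-3.34) turned to 1.98 without non-diabetic donor 1.

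In T cell-like cells edgeR called 0 of 10999 genes, with 256 at an unadjusted p under 0.05 where chance gives 550, DESeq2 called 12 and limma-voom 0. Groups did not overlap for 1517 genes (13.8%), against 20% by chance. Leaving out diabetic donor 2, non-diabetic donor 1 or non-diabetic donor 3 gave 14, 4 and 17 genes, and the earlier deposit alone (2 diabetic donors against 1) gave 27. Cells lay mostly in cluster 11 in diabetic donor 1 (47.7%), cluster 9 in diabetic donor 3 (80.4%), cluster 10 in non-diabetic donor 1 (55.9%), and clusters 4 and 6 in diabetic donor 2 and non-diabetic donor 3. Camera called 13 lists, and 0 with an estimated correlation. Macrophage markers led, with a median log2 fold change of 3.16 (9 genes, 7 higher adjusted over the list alone, camera adjusted p = 6.16e-21, adjusted p = 0.234 with an estimated correlation). MHC class II genes followed (8 genes, 4 higher adjusted over the list alone, median 1.69, camera adjusted p = 8.64e-15, adjusted p = 0.26 with an estimated correlation). Next came immediate early genes (18 genes, 2 higher adjusted over the list alone, median 1.08, 9.3e-11, adjusted p = 0.327 with an estimated correlation) and resident perivascular macrophage genes (5 genes, median 2.63, or 2.89 at bounds, 1.28e-07, adjusted p = 0.234 with an estimated correlation). Lipid-associated macrophage (14 genes, median 0.52, 5.88e-06), synthetic smooth muscle (5 genes, 1.94, 2.88e-06), endothelial ligand (9 genes, 0.88, 2.04e-05), adhesion and NF-kB (8 genes, 0.45, 0.000101), macrophage-derived factor (7 genes, 0.71, 0.000331), inflammatory macrophage (7 genes, 1.40, 0.000525), plasma cell marker (3 genes, 3.68, 0.00268) and matrix genes (9 genes, 0.61, 0.0242) lay higher, and ribosomal protein genes lower (82 genes, -0.30, 8.91e-06), by camera. Their adjusted p with an estimated correlation lay between 0.234 and 0.517. In this comparison monocyte and erythroid markers were not called (median -0.63 and 2.01, camera adjusted p = 0.758 for each).

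Whole arteries were not tested for diabetes, with 1 diabetic donor, and the intervals given cover counting error only. Macrophage-like cells of the diabetic artery held TREM2 at 322 CPM (exact Poisson 95% interval 259 to 395) and those of non-diabetic artery donor 1 at 131 (94.7 to 176). APOE stood at 1521 (1382 to 1671) and 295 (239 to 360), SPP1 at 2752 (2563 to 2951) and 1181 (1067 to 1305), and CCL4 at 797 (697 to 908) and 128 (92.2 to 173). The diabetic artery differed from the non-diabetic one in the direction seen between intima groups for 20 of the 24 genes named by rule in macrophage-like cells, and for 13 of 24 in endothelial-like cells. CCL2, higher in value in diabetic intimal endothelial-like cells, stood at 2.81 CPM (0.340 to 10.1) in the diabetic artery and at 30.8 (19.9 to 45.5) and 41.5 (24.96 to 64.7) in the non-diabetic ones. VIPR1 had 1 UMI in 1 non-diabetic artery and 0 in the others, too few to compare.

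Whole arteries held more smooth muscle-like and glial-like cells in value, and the intima more lymphocytes. Smooth muscle-like cells made up 0.0308% ± 0.0434 of intimal (SD, n = 6) and 17.3% ± 13.2 of whole-artery cells (n = 3). Glial-like cells made up 0% and 7.20% ± 11.53, NK cell-like cells 5.18% ± 4.22 and 0.0968% ± 0.101, and erythroid-like cells 4.66% ± 10.2 and 0%. For each of these the two-sided exact permutation test gave p = 0.0238, the smallest value possible, and an adjusted p of 0.0714 over 12 classes, so none passed. T cell-like cells made up 21.4% ± 11.8 and 1.94% ± 0.612 (exact permutation p = 0.0714) and B cell-like cells 1.98% ± 2.16 and 0.163% ± 0.248 (exact permutation p = 0.0476, 0.114 adjusted). Shares of endothelial-like (22.2% ± 12.3 and 22.2% ± 6.91), macrophage-like (17.4% ± 12.998 and 9.78% ± 1.49) and fibroblast-like cells (11.4% ± 25.1 and 17.7% ± 13.9) overlapped (exact permutation p = 0.952, 0.452 and 0.69).

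Endothelial-like cells of the intima and of whole arteries differed in 784 of 9091 genes by edgeR. F5, which encodes coagulation factor V, was at least 72.2-fold higher in the intima (n = 6) than in whole arteries (n = 3), against 3 UMIs over the whole-artery group, where it had none. On the same basis SCX, a tendon transcription factor gene, was at least 59.1-fold higher, PDE3A 54.7-fold, ESM1 49.9-fold and NRG1 45.6-fold. ITLN1, GDF7 and CYP4X1, with 1 to 2 UMIs in whole arteries, had ratios of 1623 (95% counting interval 291 to 64110), 317 (87.8 to 2620) and 256 (45.9 to 10105). BTNL9 (ENSG00000165810, chromosome 5, 181040225 to 181061523) fell by 8.34 ± 0.63 on the log2 scale in the intima, to 0.537 ± 0.505 from 131 ± 84.7 CPM (edgeR adjusted p 1.58e-05). C11orf96 fell by 6.102 ± 0.43 (4.63e-06) and DNASE1L3, a DNA-degrading enzyme of venous and capillary endothelium, by 6.03 ± 0.59 (0.000198). ZNF385D, STC1, the protease gene ADAMTS9, the laminin receptor gene ITGA6 and SEMA6A fell by 4.63, 7.47, 4.91, 4.79 and 4.69.

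Of these 784 genes 492 were higher and 292 lower in the intima, with 2038 at an unadjusted p under 0.05 where chance gives 455. DESeq2 called 1320. Groups did not overlap for 1391 genes (15.3%), against 2.38% by chance. Without the diabetic whole-artery donor 300 genes passed, without non-diabetic whole-artery donors 1 and 2 519 and 518, and among non-diabetic donors 378. Of the genes named, 12 lost the call without the diabetic whole-artery donor, among them GDF7, CYP4X1, STC1, ADAMTS9 and ITGA6, and STC1 lost it without each of several intima donors. Nearly all endothelial-like cells of the arteries lay in cluster 2, which was led by ACKR1, CCL14 and FABP4 and held 18.8% of the endothelial-like cells of non-diabetic intima donor 5, while those of the other intima donors lay in clusters 1, 3, 7 and 14. No whole artery belonged to the earlier deposit.

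By list, intimal endothelial-like cells held less MHC class II and lipid uptake RNA. Of 8 MHC class II genes 5 fell, and 7 adjusted over the list alone, with a median log2 fold change of -1.72 (camera adjusted p = 1.3e-08, adjusted p = 0.283 with an estimated correlation). CIITA, the master regulator of these genes, fell by 2.66 ± 0.30 to 9.80 ± 1.94 from 63.2 ± 27.6 CPM (edgeR adjusted p 9.9e-05), and HLA-DPB1 fell to 167 ± 68.1 from 487 ± 36.5 CPM (0.00803). Of 12 lipid uptake and storage genes 4 fell, and 8 adjusted over the list alone (median -2.91, camera adjusted p = 4.06e-06, adjusted p = 0.283 with an estimated correlation). GPIHBP1, which holds lipoprotein lipase on capillary walls, fell by 8.75 ± 0.95 (edgeR adjusted p 0.000432), the fat cell regulator PPARG by 3.27 (0.00262) and the lipoprotein receptor gene SCARB1 by 3.37 (0.00422). PPARG and SCARB1 lost the call without the diabetic whole-artery donor. FABP4 stood at 24.2 ± 48.9 and 1606 ± 824 CPM and CD36 at 10.5 ± 24.1 and 309 ± 264 CPM without a call (edgeR adjusted p 0.0763 and 0.166). FABP4 also led the mostly intimal unnamed cluster 20, whose cells were not counted here.

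Matrix genes moved both ways between the preparations. Of 18, 6 rose and 2 fell in the intima, and 8 and 4 adjusted over the list alone (median 1.47, camera adjusted p = 0.0149, adjusted p = 0.735 with an estimated correlation). SULF1, which trims sulfate from heparan chains, rose by 5.42 ± 0.47 to 1492 ± 375 from 36.8 ± 12.3 CPM (edgeR adjusted p 1.08e-05) and the proteoglycan gene BGN by 5.80 ± 0.68 to 1320.5 ± 547 from 22.4 ± 21.6 (0.000178). FN1 rose by 3.35 (0.0118). SNAI1 fell by 2.48 (0.0006) and ACTA2, which is also a smooth muscle marker, by 2.73 (0.0141). Markers of smooth muscle (3 genes, 1 lower, median -0.72, camera adjusted p = 0.184), fibroblasts (6 genes, 1 higher, 1.95, 0.125), macrophages (5 genes, 1 higher, -1.43, 0.638) and erythroid cells (3 genes, 9.62, or 8.38 at bounds, 0.225) were not called as lists in these cells. Of 13 quiescence genes 2 rose, and 3 adjusted over the list alone (median 0.22, camera adjusted p = 0.0663). The 2 were PTGIS, which makes prostacyclin (4.58 ± 0.52, edgeR adjusted p 9.85e-05), and PROCR, the endothelial protein C receptor (2.74 ± 0.46, 0.00175). NOS3 stood at 127 ± 76.1 and 48.6 ± 22.4 CPM (edgeR adjusted p 0.0577). Of 14 angiogenesis genes 2 rose and 3 fell (median -0.58, camera adjusted p = 0.625), with UNC5B up by 3.62 and the Notch targets and ligands HEY1 and DLL4 down by 4.34 and 1.94. Of the endothelial ligands GAS6, a ligand of macrophage receptors that clear dead cells, rose by 2.54 to 866 ± 264 from 156 ± 48.3 CPM (edgeR adjusted p 0.00194) and SELP by 1.88 (0.0362), among 2 higher and 2 lower of 16. Of the endothelial receptors TGFBR2 fell by 1.68 (0.00836) and ACVRL1 rose by 1.53 (0.011). SELP, DLL4, TGFBR2 and ACVRL1 lost the call without the diabetic whole-artery donor and SELP and DLL4 also without non-diabetic intima donor 1. VCAM1, ICAM1, SELE, KLF2 and CCL2 were not called (edgeR adjusted p 0.701, 0.848, 0.497, 0.988 and 0.614), and ICAM1 and KLF2 changed sign between donors left out. Ribosomal protein (81 genes, 5 lower, median -0.71, camera adjusted p = 2.34e-09, adjusted p = 0.742 with an estimated correlation) and mitochondrially encoded genes (13 genes, 1 lower, median -0.80, camera adjusted p = 0.00322, adjusted p = 0.735 with an estimated correlation) lay lower in the intima, and immediate early genes showed no shift (18 genes, median -0.08, camera adjusted p = 0.814).

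**Figure D4:**
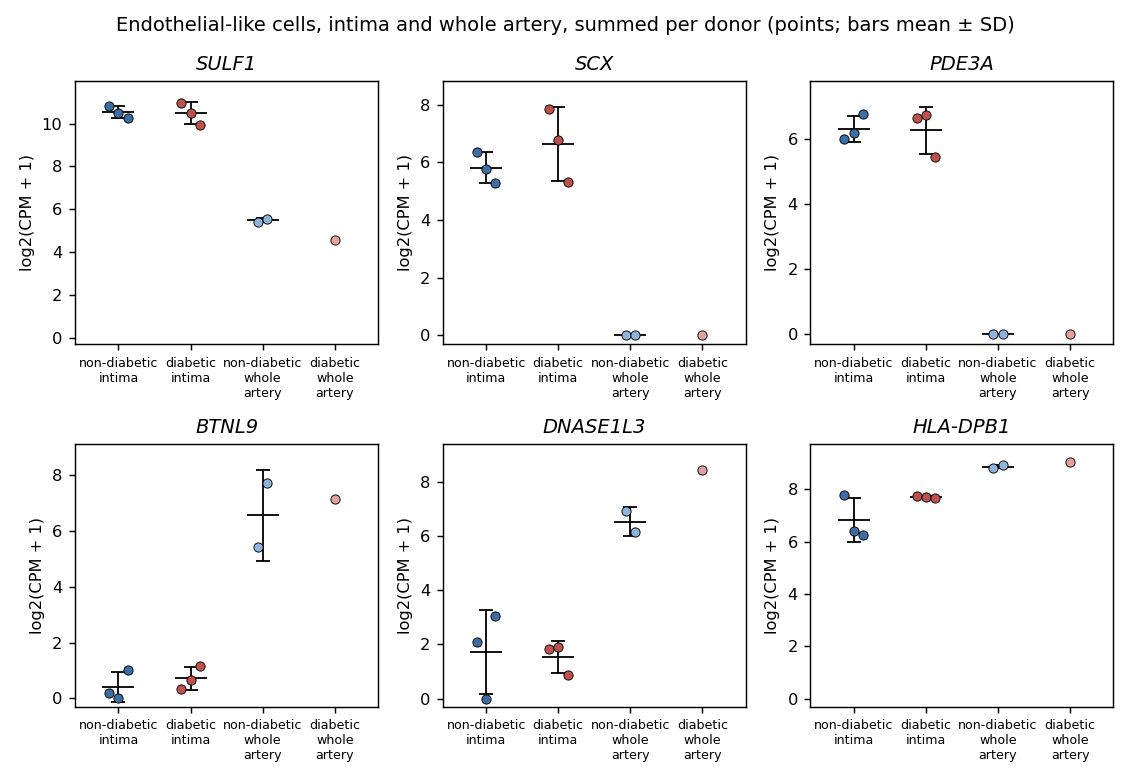
SULF1, SCX, PDE3A, BTNL9, DNASE1L3 and HLA-DPB1 as log2(CPM + 1) in endothelial-like cells of 6 intima and 3 whole-artery donors, by group, with 1 point per donor and bars for the mean and SD of groups of 2 or more donors. On the CPM scale SULF1 averages 1492 in the intima and 36.8 in whole arteries.

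Macrophage-like cells of whole arteries carried more smooth muscle RNA than those of the intima, beside the far larger smooth muscle share of whole arteries. TPM2, which encodes muscle tropomyosin, fell by 5.00 ± 0.45 in the intima to 5.98 ± 3.91 (SD, n = 5) from 181 ± 85.6 CPM (n = 2; edgeR adjusted p 0.000362), TAGLN by 3.87 ± 0.48 (0.0059), ACTA2 by 3.65 (0.00653), MYL9 by 4.51 (0.00532) and CALD1 by 4.81 (0.0164). The matrix gene SPARCL1 and the protease gene HTRA1 fell by 4.67 and 3.09 (0.00279 for each), and HEXIM1, SYNE1 and PRKX by 2.28, 2.16 and 1.87. In the intima PLA2G7, a lipoprotein-associated phospholipase, was at least 12.6-fold higher against 3 UMIs over the whole-artery group, and SMPDL3A and CD72 had ratios of 36.5 (95% counting interval 6.55 to 1444) and 11.4 (3.88 to 55.2). HES1, a Notch target, rose by 2.98 (0.0381), the immune receptor gene CD48 by 2.89 to 133 ± 44.2 from 18.5 ± 1.46 CPM (0.0266) and SASH1 by 2.63 (0.0273). TREM2 stood at 95.5 ± 47.8 and 221 ± 142 CPM (log2 fold change -1.28 ± 0.35, edgeR adjusted p 0.199), APOE at 3717 ± 2449 and 895 ± 883 (0.15) and SPP1 at 474 ± 786 and 1917 ± 1179 (0.773). TYROBP, GPNMB, CD9, LYVE1 and IL1B were not called, with log2 fold changes of 0.29, 1.34, -1.66, 0.24 and -1.10. LYVE1 turned to -0.03 without diabetic intima donor 3, TYROBP to -0.33 without non-diabetic intima donor 1 and IL1B to 0.55 without the diabetic whole-artery donor.

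EdgeR called 29 of 9532 genes in this comparison of macrophage-like cells, 7 higher and 22 lower in the intima, with 882 at an unadjusted p under 0.05 where chance gives 477, and DESeq2 called 128. Groups did not overlap for 1780 genes (18.7%), against 9.52% by chance. Without the diabetic whole-artery donor 0 genes passed and without non-diabetic whole-artery donor 1 only TPM2 did, while 48 passed among non-diabetic donors (each leaves 1 whole-artery donor, assumed to vary like the intima donors). In turn 54, 57 and 16 passed without diabetic intima donors 1 and 2 and non-diabetic intima donor 1. Contractile smooth muscle genes (8 genes, 4 lower, and 8 adjusted over the list alone; median -4.79, camera adjusted p = 2.81e-41), smooth muscle markers (6 genes, 3 lower, and 6 adjusted over the list alone; median -4.64, camera adjusted p = 2.48e-33) and matrix genes (9 genes, 2 lower, and 2 adjusted over the list alone; median -1.86, camera adjusted p = 7.12e-10) kept their call with an estimated correlation (adjusted p = 0.00694, 0.00694 and 0.0254). Fibroblast markers (4 genes, 0 lower, and 4 adjusted over the list alone; median -4.66, camera adjusted p = 4.45e-08, adjusted p = 0.163 with an estimated correlation) and synthetic smooth muscle genes (7 genes, median -2.43, camera adjusted p = 0.00642, adjusted p = 0.379 with an estimated correlation) lay lower. Monocyte markers (7 genes, median 1.27, camera adjusted p = 0.00642, adjusted p = 0.197 with an estimated correlation), plasma cell markers (5 genes, 10.79, or 5.20 at bounds, 0.00273, adjusted p = 0.562 with an estimated correlation) and erythroid markers (3 genes, 9.77, 0.0439, adjusted p = 0.714 with an estimated correlation) lay higher in the intima. The lipid-associated list showed no shift (18 genes, 2 higher and 2 lower adjusted over the list alone, median 0.33, camera adjusted p = 0.724).

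Fibroblast-like cells of whole arteries held genes of a cluster that the intima lacked. SCN7A, a sodium channel gene of nerve-associated cells, was at least 227-fold lower in the intima (n = 3) than in whole arteries (n = 3), against 3 UMIs over the intima group. With 1 to 3 UMIs in the intima, the keratin gene KRT19, TNNC1, the laminin receptor gene ITGA6, C19orf33 and COL15A1 were lower there by ratios of 628 (95% counting interval 112 to 24858), 482 (85.9 to 19094), 84.4 (22.8 to 705), 66.1 (17.8 to 555) and 43.1 (14.2 to 213). PTGDS, which makes prostaglandin D, fell by 4.47 ± 0.62 to 966 ± 421 from 21295 ± 11417 CPM (edgeR adjusted p 0.0237), the tight junction gene CLDN1 by 5.42 (0.0341), the early response gene EGR1 by 3.33 (0.0237) and TPM2 by 3.00 (0.0402). In the intima COL12A1, a fibril-associated collagen, rose by 2.49 ± 0.42 to 394 ± 127 from 76.2 ± 20.6 CPM (0.0484), the long non-coding RNA CYTOR by 2.86 (0.0254), the zinc transporter gene SLC39A14 by 2.81 (0.0307) and MEG8, PALM and VASN by 2.74, 2.40 and 2.26, with MEG8 at 1.55 without non-diabetic intima donor 5. ALDH1A3 and METRNL had log2 fold changes of 2.39 and 2.30 (0.0569 and 0.0743). Whole-artery cells lay in clusters 5 and 24, the latter led by PTGDS, KRT19, TNNC1 and SCN7A, apart from 7.21% of those of non-diabetic artery donor 1 in cluster 21. Intimal cells lay in clusters 5, 21 and 34.

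EdgeR called 16 of 3777 genes between fibroblast-like cells of the preparations, 6 higher and 10 lower in the intima, with 370 at an unadjusted p under 0.05 where chance gives 189, and DESeq2 called 110. Groups did not overlap for 643 genes (17.0%), against 10% by chance. Without diabetic intima donor 3 or non-diabetic intima donor 5, 0 genes passed, 2 without the diabetic whole-artery donor, 6 without diabetic intima donor 2 and 38 without non-diabetic whole-artery donor 1, and 0 passed with the stricter cell filter. Immediate early genes (16 genes, 1 lower, and 4 adjusted over the list alone; median -0.88, camera adjusted p = 4.3e-07, adjusted p = 0.411 with an estimated correlation), contractile smooth muscle genes (7 genes, 1 lower, and 2 adjusted over the list alone; median -0.999, 7.63e-06, adjusted p = 0.292 with an estimated correlation) and smooth muscle markers (5 genes, 3 adjusted over the list alone; median -1.32, 0.000436, adjusted p = 0.303 with an estimated correlation) lay lower in the intima. Among the early genes FOS and BTG2 had log2 fold changes of -2.76 and -2.91 (edgeR adjusted p 0.07 and 0.1), and TAGLN one of -2.10 (0.171). Adhesion and NF-kB genes (3 genes, 2 higher adjusted over the list alone; median 1.01, camera adjusted p = 0.0457, adjusted p = 0.411 with an estimated correlation) and metallothioneins (7 genes, median 0.65, camera adjusted p = 0.0316, adjusted p = 0.504 with an estimated correlation) lay higher, and ribosomal protein genes slightly lower (80 genes, median -0.19, camera adjusted p = 0.0457, adjusted p = 0.906 with an estimated correlation).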

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

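The tests of the macrophage-like share and of other splits of the donors were chosen after the result was seen, while the tests of early response genes and of vessel types were written before their own values were computed. Across 80 groups of 4 to 10 donors, 15 had a donor far from the others by Dixon's rule, and chance flags about 1 in 20 groups, or 4 here. In intimal endothelial-like cells non-diabetic donor 5 stood highest and apart for STC1 (28.8 CPM), SEMA6A (28.8 CPM), CD36 (59.7 CPM), FABP4 (123.4 CPM) and GPIHBP1 (2.06 CPM), and 18.8% of its endothelial-like cells lay in cluster 2. Diabetic donor 1 stood highest for SCX (230.4 CPM) and BGN (2350.0 CPM), and diabetic donor 3 stood highest for ICAM1 (246.0 CPM) and SELE (120.3 CPM) and lowest for GAS6 (353.9 CPM). In macrophage-like cells diabetic donor 3 stood highest for SMPDL3A (124.2 CPM), SPP1 (1869 CPM) and FBLN1 (2.86 CPM), diabetic donor 2 for ACTA2 (9.11 CPM) and non-diabetic donor 3 for SFRP2 (10.5 CPM).

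In donors too shallow for the comparisons, shares under the looser and the main cell filter, in this order, differed. Non-diabetic intima donor 4 had 48.1% endothelial-like and 22.6% T cell-like cells (106 cells), and 5.88% and 13.7% (51 cells). Diabetic intima donor 4 had 80.1% endothelial-like and 7.13% macrophage-like cells (729 cells), and 2.63% and 11.8% (76 cells). In endothelial-like cells of the diabetic whole artery, 5 genes lay opposite to the intima direction against both non-diabetic arteries, a difference that was not tested: MRPS6 (9.82 CPM), MARCKS (87.0 CPM), PGM5 (124.8 CPM), MFSD6 (43.5 CPM) and CCL2 (2.81 CPM).

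The higher macrophage-like share of diabetic intima could reflect diabetes, the choice of donors or other cells diluting the macrophages. Under the looser cell filter, which lets in donor 4 of each group, diabetic shares were 7.13% in donor 4 and 22.8% to 32.8% in the others, and non-diabetic shares 0% in donor 4 and 2.84% to 8.50% in the others. The groups then overlapped by 1 donor, as the choice of donors would give, while the mean difference was 18.5 percentage points (exact permutation p = 0.0571). Among immune cells other than neutrophils and erythroid cells the lowest diabetic share was 41.0% and the highest non-diabetic 40.0%, from a donor with 35 such cells, so dilution can be neither excluded nor shown. Diabetes was therefore not separated from these.

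Early response and inflammatory genes, higher in value in diabetic endothelial-like and macrophage-like cells, could reflect handling of the tissue, free RNA, the deposit or diabetes. In NK cell-like cells the immediate early list had a median log2 fold change of 1.70 (16 genes, 8 higher adjusted over the list alone, camera adjusted p = 2.85e-12, adjusted p = 0.347 with an estimated correlation), as handling of the whole tissue would give, though a response of all cells in the donor would give it too. Free RNA from macrophages was excluded as the only source in endothelial-like cells, where the inflammatory list stood between 2.75 and 6.26 times as high relative to macrophages as the macrophage markers did, and the immediate early list stood at 117% to 300% of its macrophage level against 0.209% to 1.48% for the markers. A term for the earlier deposit kept 90.0% and 105% of the list medians, but with groups nearly balanced for it this decided nothing. No cause was excluded.

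Lower capillary genes in intimal endothelial-like cells could reflect different vessels, the deposit and preparation of whole arteries, or naming. Unnamed cluster 20, led by RBP7, RGCC and others, held 143 non-diabetic and 147 diabetic intimal cells, and 17 and 6 whole-artery cells. The capillary list, chosen after the first results, had a median of -1.85 (6 genes, 2 lower, camera adjusted p = 1.25e-05, adjusted p = 0.026 with an estimated correlation), with RBP7 down by 2.25 and CA4 absent from the intima donors compared. The arterial list had a median of 0.07 (8 genes, GJA5 and BMX among 2 higher, 2 lower, camera adjusted p = 0.665) and the venous list one of -0.80 (8 genes, 2 higher, 1 lower, camera adjusted p = 0.462), so the test, which asked for all 3, could not tell. Vessel types thus stay open, and no other biological explanation was tested.

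Other splits of the same donors were counted. For intima against whole artery in endothelial-like cells 1 of 84 splits, the real one, gave as many as 784 genes, and the highest other gave 5. For gene lists called by camera 69 of the 84 gave at least the real 5, with 14 as the highest other, so chance is not excluded for those lists. For diabetes in endothelial-like cells 10 splits are too few to judge: 4 of 10 gave at least the real 1 gene, and diabetic donors 1 and 2 with non-diabetic donor 3 against the rest gave 70, which points to a structure of the samples other than diabetes. For gene lists 4 of 10 splits gave at least the real 15, with 16 as the highest other. For fibroblast-like cells 9 splits were too few as well, with 16 genes in the real one, reached by 1 of 9, and 1 gene in the highest other. Their lists numbered 6 in the real split, a count reached by 3 of 9, with 7 as the highest other.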

How the results depend on the processing

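Of 205 results on named genes, 191 never changed direction in the settings run for them, which differ by result and come from 30 planned settings and 8 chosen after the data were seen. Of 3768 values under alternatives 3716 kept their direction, 52 took the other, 229 lost the call and 301 gained it. The later-deposited donors alone (1 against 1) leave no replicate and were not run. Unless stated, the cause was not tested. Depth limits the 4 shallow donors, the shares of cells with a TREM2 UMI, and genes near 0 in whole arteries.

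Genes called between diabetic and non-diabetic intima were few and unstable. In endothelial-like cells (1 gene) there were 80 with DESeq2, 131 without the filter on low counts, 3 with the looser cell filter, 117 by each cell's own markers, 12 with a minimum of 50 cells and 50000 UMIs, 5 with the term for the earlier deposit, 156 in its donors alone, 0 with whole arteries and a preparation term and 21 with libraries in limma-voom, and 0 to 20 without 1 donor. In macrophage-like cells (0 genes) there were 45 with DESeq2, 203 without the filter, 5 with the stricter cell filter, 5 with a minimum of 10 cells and none on UMIs, 6 with the term for the deposit, 38 in its donors alone, 1 with libraries in limma-voom, 5 with 3 myeloid classes pooled and 57 with DESeq2 on the pool (chosen after the data were seen), and 0 to 26 without 1 donor. In T cell-like cells (0 genes) there were 12 with DESeq2, 37 without the filter, 27 in the donors of the earlier deposit and 2 with a preparation term, and 0 to 17 without 1 donor. With the replicate number as a block the counts were 57, 192 and 83, but with 2 shared numbers the correlations of deviations (0.127 and -0.184, 0.317 and 0.0898, 0.540 and 0.0991) did not show that the numbers pair. Lists called by camera numbered 0, 0 and 0 with an estimated correlation, and 9 to 14 in endothelial-like cells (15), 13 to 18 in macrophage-like cells (16) and 12 to 16 in T cell-like cells (13) without 1 donor.

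Between intima and whole artery, endothelial-like cells (784 genes) had 1320 with DESeq2, 1968 without the filter, 378 in non-diabetic donors and 300 to 880 without 1 donor. Macrophage-like cells (29) had 128, 249, 8 with the stricter and 19 with the looser cell filter, 48 in non-diabetic donors, and 0 to 57 without 1 donor, and fibroblast-like cells (16) had 110, 398, 0 with the stricter filter, 5 by each cell's own markers and 0 to 38 without 1 donor. A lone donor left in a group is assumed to vary like the others.

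Log2 fold changes that took the other sign between diabetic and non-diabetic intima were those of VCAM1 (-0.38 in the earlier deposit; -0.92 to 1.15 without 1 donor), ICAM1 (-0.42 in the earlier deposit; -0.41 to 0.63), SELE (-1.39 with limma-voom, -1.08 in the earlier deposit, -2.50 with libraries; -0.78 to 11.33), KLF2 (-0.00215 with the block; -6.59e-04 to 1.07), SPP1 (-0.56 to 3.70), CD9 (-0.24 in the earlier deposit; 0.48 to 6.47), S100A12 (0.44 with the stricter filter, 0.84 with doublets kept) and IFI27 (0.16 with libraries; -4.24 to 1.98). TYROBP, at -0.00119, took 0.00359 with DESeq2, 0.38 with limma-voom, 0.0683 without the filter, 0.21 and 0.11 with the stricter and looser cell filters, 0.0396 with doublets kept, 0.25 with that minimum of 10 cells, 0.12 with the deposit term, 0.0641 with a preparation term, 0.51 with the block, 0.23 with libraries, 0.0880 and 0.0593 with the pool in edgeR and DESeq2, and -0.71 to 1.62 without 1 donor.

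Between intima and whole artery ICAM1 took -0.0179 with the looser filter and -0.0037 in non-diabetic donors (-0.0987 to 0.38 without 1 donor), KLF2 -0.00224, -0.36, -0.21 and -0.17 with the stricter filter, the looser filter, own markers and non-diabetic donors (-0.20 to 0.22), LYVE1 -0.37 and IL1B 0.76 with the looser filter (-0.14 to 0.49 and -1.94 to 0.55), IL1B also 0.46 in non-diabetic donors, and TYROBP -0.33 to 0.58. The difference in endothelial-like share, -0.073 points, was 6.36, 13.3 and 7.35 with the stricter filter, the looser filter and own markers, 0.258 without erythroid-like cells (chosen after the data were seen) and -3.28 to 3.59 without 1 donor. Between diabetic and non-diabetic intima it ran from -3.03 to 13.7, the T cell-like difference from -0.0738 to 16.1, and that of cells with a TREM2 UMI from -0.966 to 1.77 without 1 donor and -0.155 with the looser filter.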

Other observations

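For T cell-like cells 2 hypotheses of this re-analysis were tested, with tests written before their values were computed. Macrophage markers, higher by camera in T cell-like cells of diabetic intima, could come from free RNA in proportion to each library's macrophage RNA, or from doublets of T cells and macrophages. Relative to their level in all cells of the same donor, the markers differed by 0.364 on the log2 scale between the groups, within the limit of 1 set for free RNA in proportion, and by -0.621 without diabetic donor 1, whose relative level of 8.39% stood apart from 1.96% to 3.56% in the other 4. The richest 5% of T cell-like cells held between 57.9% and 79.5% of the marker UMIs of a diabetic donor, and 77.6% and 67.7% of those of the 2 non-diabetic donors. UMIs were thus gathered in few cells in both groups, which does not tie doublets to the difference, and doublets stay open beside free RNA.

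Naive T cell genes, a list of 7 chosen after the first results, had a median log2 fold change of -1.40 in diabetic T cell-like cells (camera adjusted p = 9.19e-14, adjusted p = 0.00577 with an estimated correlation, fry adjusted p = 0.0243). Their mean log2 CPM was between 5.75 and 5.96 in 3 diabetic donors, and 7.56 and 6.77 in 2 non-diabetic donors. Blood carried into the preparation, which brings naive T cells, could give this. The values go against it where hemoglobin marks blood: diabetic donor 3 (21.2% hemoglobin) lay at a difference of -1.66 log2 units from non-diabetic donor 1 (7.61%) and at 5.90 beside 5.75 and 5.96 in the diabetic donors near 1%, and non-diabetic donor 3 (70.0%) lay below donor 1. They rest on 1 hemoglobin-rich donor in each group, so blood is not excluded.

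With deeper thinning, chosen after the data were seen, macrophage-like cells with a TREM2 UMI made up 9.52% ± 1.60 in diabetic (SD, n = 3) and 7.47% ± 3.07 in non-diabetic intima (n = 2) at 1000 UMIs (exact permutation p = 0.4), where 804 of 3011 diabetic and 76 of 243 non-diabetic cells were too shallow and were left out, and 17.3% ± 2.98 and 9.46% ± 0.483 at 2000 UMIs (exact permutation p = 0.2, the smallest value possible), where 1407 and 116 were left out and 1 donor kept 22 cells.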
